A study of Homo sapiens with 6 samples.

How the data were processed

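Total RNA of DLD1 cells infected with control shRNA or CDKL1 shRNA lentivirus was extracted with TRIzol, per the labels' protocols, and biotin-labelled cRNA made from 6 µg of it was hybridised to Affymetrix expression arrays. The deposited table holds log2 expression values, 1 column per array and 49395 probe sets per column. Per the submitters' processing notes the authors made these values with RMA, which corrects background within each array, quantile-normalises between arrays and summarises probes to 1 log2 value per probe set. The version of RMA and its settings are not given in the sources used here. RMA compresses changes of dim probe sets towards 0, and its normalisation assumes that most genes do not change. No detection calls were used, and scanner files were not analysed here, so levels near the background were judged against the background control probe sets in the same table.

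Probe sets were named through the platform's annotation table, in which 44988 had 1 gene symbol, 1832 had several and 2473 non-control probe sets had none. No gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 44961 had an Entrez identifier found in the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed updating. The build behind the array's probes is not given in the sources used here, and coordinates are not reported. The 102 control (AFFX) probe sets were left out of the gene tests. Each of 18132 genes was represented by its probe set of 1 symbol with the highest mean over the 6 arrays, chosen without regard to group, and no filter on dim genes was applied. Probe sets with the suffix _s or _x can bind transcripts of related genes, so members of near-identical families are uncertain. 0 columns of per-sample values were left unused.

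The 6 arrays formed 2 groups of 3 from the sample titles and descriptions. The design text calls the samples of a group independent, but no label says whether they came from separate infections or cultures, so p-values measure the spread between these samples, which may be partly technical. A linear model with group as its only term was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p was adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. A second count added a fold of at least 1.5. Single values were compared with exact two-sided permutation tests, whose smallest p with 3 arrays against 3 is 0.1. RNA quality was read from the 3' minus 5' log2 differences of the ACTB and GAPDH control probe sets. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

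Before the data were examined, 30 gene lists with 661 members were written, of which 605 members were measured. The lists covered the CDKL family, DNA replication and G1/S, G2/M and mitosis, cell cycle inhibitors and p53 targets, apoptosis, DNA damage repair, interferon, NF-kappaB, epithelial, mesenchymal, colonocyte, Wnt, MAPK, Hedgehog and cilium genes. They also covered the unfolded protein response, ATF4, cholesterol synthesis, glycolysis, oxidative phosphorylation, ribosome biogenesis, replication-dependent histones, autophagy, heat shock, NRF2, RNA interference, and markers of fibroblasts, leukocytes, endothelium, and kidney-line or neural cells. Each list was tested with camera in limma at a preset correlation of 0.01, adjusted over the 30 lists. The CDKL list held 4 measured genes, with a camera adjusted p of 0.972.

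The rule for named genes was also fixed beforehand. It took the CDKL genes, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap, and up to 4 members with the smallest adjusted p from each list that passed or held at least 3 called genes. Genes outside this rule are said to have been chosen after their values were seen, or are further called members of the same passing lists.

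The fit was tested on simulated data built on the 18132 genes of this comparison. Of 50 genes changed by each fold, 64% were recovered at 1.25-fold and 100% at 1.5-fold, 2-fold and 3-fold, and 12 unchanged genes were called, 6.19% of all calls. Far fewer genes were changed here than the 3040 called in the real comparison, so these shares hold for the simulated setting only. When 1 of 30 simulated lists was shifted by 0.2 on the log2 scale, camera called it with the preset (adjusted p = 1.69e-36) and with an estimated correlation (adjusted p = 0.00383), as did fry (adjusted p = 0.000663), and 0 other lists were called with the preset. The noise of each simulated gene was drawn independently, so these lists held no correlation between genes. The simulation therefore cannot tell whether the preset or an estimated correlation suits the real lists.

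Alternatives fixed before the data were examined were a block for the replicate number, leaving out each array, a further quantile normalisation, subtraction of each array's median, restriction to genes brighter than the median gene, the mean of a gene's probe sets or every probe set, other variance models, array weights, a per-gene two-sample test, a threshold of 0.01, and the list tests with an estimated correlation or fry. The ACTB 3' minus 5' difference as a covariate, and leaving out each array for the RNA quality values, were added after the data were seen.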

Results

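Gene expression was measured in DLD1 cells, an established human colorectal adenocarcinoma line, after infection with lentivirus that expressed a short hairpin RNA (shRNA) against CDKL1 or a control shRNA. CDKL1 (cyclin-dependent kinase-like 1) is a serine/threonine kinase related in sequence to the cyclin-dependent kinases. A short hairpin RNA is processed in the cell into a small interfering RNA that directs degradation of a matching transcript. Each group held 3 samples, and total RNA of each was hybridised to 1 Affymetrix expression array, which gave 6 arrays in all. The values were log2 expression values that the authors had normalised between arrays by RMA, and 18132 genes were each read from 1 probe set. Array medians over all probe sets lay between 6.64 and 6.70. Across probe sets, which are not independent replicates, arrays of the same group correlated at r = 0.99802 to 0.99873 and arrays of different groups at r = 0.99563 to 0.99658. The first principal component held 55.8% of the variance and separated the 3 CDKL1 shRNA arrays from the 3 control arrays. With 3 arrays per group, the number of arrays limits the precision of every value.

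The question the design poses is which genes change in colorectal cancer cells that express an shRNA against CDKL1, so the targeted gene was examined first. CDKL1 was read by probe set 11741692_a_at at a log2 level of 4.37 ± 0.18 in control arrays and 4.17 ± 0.09 in CDKL1 shRNA arrays (SD, n = 3 each). The log2 change was -0.19 with a 95% interval from -0.41 to 0.03, or -12.6% with an interval from -24.9% to 1.77%. It did not pass the test (limma, adjusted p = 0.219), and an exact two-sided permutation test of the 6 values gave p = 0.3, where the smallest p that 3 arrays against 3 allow is 0.1. Without control shRNA replicate 3 the log2 change was -0.29, and it then passed (adjusted p = 0.0489), whereas without control shRNA replicate 1 it was -0.12 (adjusted p = 0.45). The mean level of 4.27 stood at percentile 10.0 of all gene means, and background control probe sets with 10 to 16 G or C bases had means of 2.97 to 4.92. This probe set therefore could not be used to check the knockdown, and the groups are named as the labels give them. Of the related kinases, CDKL2 had a log2 change of 0.07, CDKL3 of 0.08 and CDKL4 of -0.11. By their brightest probe sets none of the 4 measured CDKL genes passed the limma test, and 0 had an unadjusted p under 0.05. The other probe sets of CDKL2, CDKL3 and CDKL4 differed in sign. Of the 10 probe sets of CDKL3, 2 had an unadjusted p under 0.05, with log2 changes of -0.16 and -0.18 (limma, adjusted p = 0.0979 and adjusted p = 0.138 over all probe sets).

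Signs of RNA quality differed between the groups. The 3' minus 5' log2 difference of the ACTB control probe sets was 1.40 ± 0.013 in control arrays and 1.60 ± 0.115 in CDKL1 shRNA arrays (SD, n = 3 each), a difference of 0.198 with an exact two-sided permutation p of 0.1. For the GAPDH control probe sets the values were 0.203 ± 0.018 and 0.275 ± 0.0262, a difference of 0.0722 with the same exact p of 0.1, the smallest possible here. CDKL1 shRNA replicate 2 had the highest ACTB value, 1.73, and without it the ACTB difference between groups was 0.132. The 21 spike-in probe sets differed between groups by -0.14 to 0.20 on the log2 scale, with a median of 0.06.

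CDKL1 shRNA was accompanied by changes in a large number of genes, most of them small. Among the largest rises were the gonadal transcription factor gene DMRT1 (5.40-fold), the hair keratin-associated protein gene KRTAP3-1 (4.97-fold), the trypsin inhibitor gene SPINK1 (4.41-fold, from a control level within the range of background controls) and the amyloid precursor protein gene APP (2.37-fold). The largest falls were those of the linker histone gene H1-4 (4.49-fold lower), the ubiquitin ligase gene NEURL1B (4.01-fold lower) and the uracil-DNA glycosylase gene UNG (3.15-fold lower). In all, 3040 of 18132 genes passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), of which 1627 were higher and 1413 lower in CDKL1 shRNA arrays (a balance that turned to 1542 and 1689 after a further quantile normalisation), with a median fold of 1.21. At least 1.5-fold changes were found for 218 of them, 125 higher and 93 lower, and at least 2-fold changes for 32, 19 higher and 13 lower. The 3 arrays of one group lay entirely above or below those of the other for 6475 genes (35.7%), against 10% by chance.

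The count of 3040 was lower without any 1 of the arrays, at 1633 to 2399, in fits that held fewer arrays and so less precision. It was 1839 without control shRNA replicate 2, 1865 without control shRNA replicate 3, 2026 without CDKL1 shRNA replicate 2 and 1633 without CDKL1 shRNA replicate 3. With the ACTB 3' minus 5' difference as a covariate, an alternative chosen after seeing the data, it was 219, 109 higher and 110 lower. Among genes changed at least 1.5-fold the median log2 change with this covariate was 0.73 for rises, as without it, and -0.78 against -0.73 for falls, while the median SE went from 0.0586 to 0.106 and from 0.0552 to 0.0995. Without CDKL1 shRNA replicate 2 the median ratio of covariate to plain change was 0.822 for rises and 1.14 for falls. The count of genes changed at least 1.5-fold was 207 to 229 with 1 array left out. It was 134 with the mean of all probe sets of a gene and 372 when a gene was counted for any called probe set. With the ACTB covariate it was 176, 87 higher and 89 lower. Of the 125 rises and 93 falls of the plain fit, 77 and 69 were still called with this covariate.

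DMRT1 rose by 2.43 on the log2 scale (SE 0.08, adjusted p = 3.03e-05, limma), from 5.61 ± 0.16 to 8.04 ± 0.07 (SD), through probe set 11727900_at. Its other probe sets, which lay at mean levels of 3.92 and 4.86, gave -0.11 and 0.05. KRTAP3-1 rose by 2.31 (SE 0.07), from 8.78 to 11.09, and both of its probe sets rose. KRTAP2-3, of the same gene cluster, rose by 1.26 (SE 0.07). SPINK1 went from 4.09 ± 0.29 to 6.23 ± 0.09 (SD), a rise of 2.14. Its control level lay within the background range of 2.97 to 4.92, so the size of this rise is not exact. APP rose by 1.25 (SE 0.07, adjusted p = 0.000141), and 13 of its 13 probe sets had a positive sign. The remaining rises in this group were H2BC4 (1.51), the scaffold protein gene AHNAK2 (1.39), the TFIIH subunit gene GTF2H3 (1.31), the alpha tubulin gene TUBA1A (1.29), the selenoprotein gene SELENOM (1.25), LY96 (1.24), which encodes the MD-2 partner of TLR4, and the carboxypeptidase gene CPA4 (1.23). Adjusted p for these 12 rises ran from 2.47e-05 to 0.000331. GTF2H3 had a median of 0.72 over its 2 probe sets, so its rise was smaller in the other one. Histone, tubulin and keratin-associated protein genes have near-identical relatives, so the values of H2BC4, TUBA1A, KRTAP2-3 and KRTAP3-1 may include signal of other family members.

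H1-4 fell by 2.17 on the log2 scale (SE 0.13, adjusted p = 0.00018, limma), from 8.71 ± 0.12 to 6.54 ± 0.26 (SD), and its value carries the same uncertainty as those of other histone genes. NEURL1B went from 8.27 ± 0.03 to 6.27 ± 0.09 (SD), a 4.01-fold fall. UNG, which removes uracil from DNA, fell by 1.66 (SE 0.05) from 10.07 ± 0.04 to 8.41 ± 0.05 (SD), in both of its probe sets. The ribosomal RNA methyltransferase gene BUD23 fell by 1.13 (SE 0.04), and all 5 of its probe sets were lower. PTK7, a catalytically inactive receptor kinase of planar cell polarity signalling, fell by 1.11, again with all 5 probe sets lower. The other falls were those of the transcription factor gene TEF (-1.20), the glycolipid transfer protein gene PLEKHA8 (-1.15), EID2 (-1.10), the splicing factor gene PRPF19 (-1.09), the cytokine gene IL33 (-1.06), the fibroblast growth factor signalling inhibitor gene IL17RD (-1.04) and HMGCS1 (-1.04). PLEKHA8 and IL17RD each had 1 of 4 probe sets with the opposite sign, at 0.12 and 0.02. Their remaining probe sets fell by far less, at -0.05 and -0.16 for PLEKHA8 and -0.21 and -0.19 for IL17RD. Each of these large falls thus came from 1 probe set. TEF had a median of -0.66 over its 2 probe sets, so its fall was smaller in the other one. These 12 falls had adjusted p from 1.88e-05 to 0.00115.

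**Figure D1:**
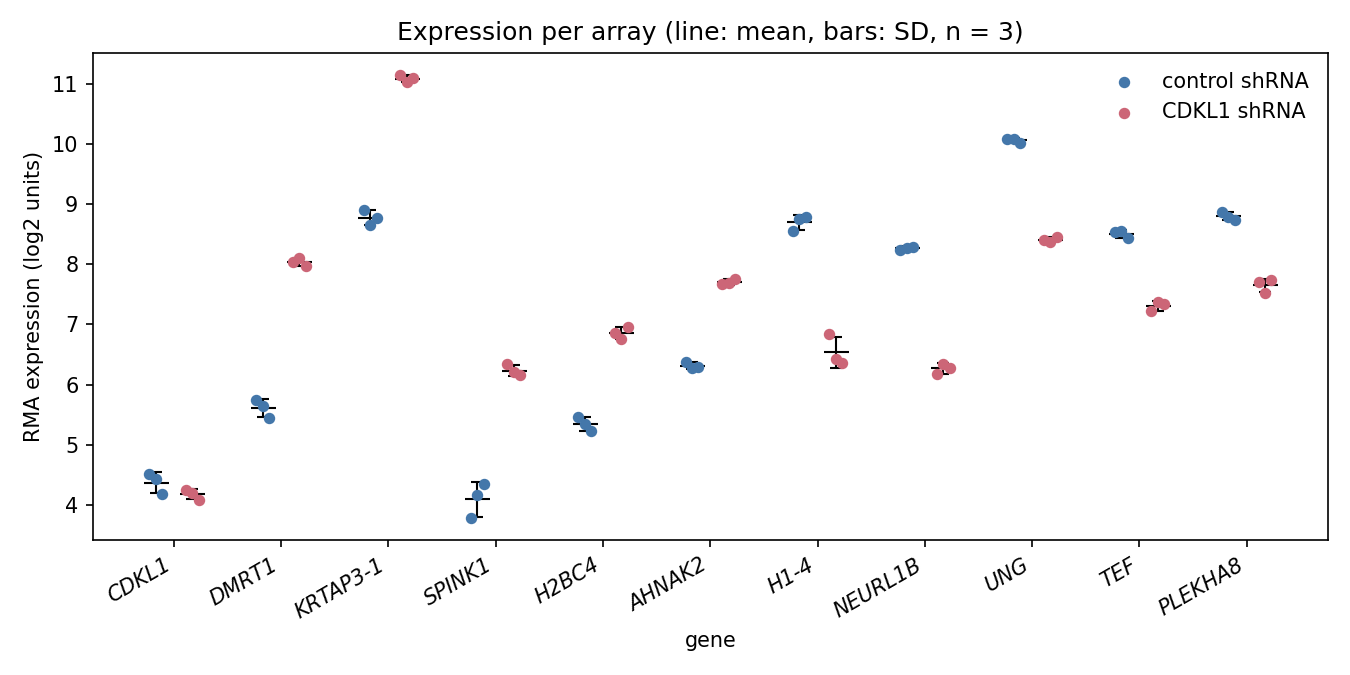
Log2 RMA expression (vertical axis) per array for CDKL1, the 5 genes with the largest rises and the 5 with the largest falls (horizontal axis), in control shRNA (blue) and CDKL1 shRNA (red) arrays; points are single arrays, lines are means and bars are SD, n = 3 per group. CDKL1 lay at 4.37 and 4.17 with overlapping arrays, whereas DMRT1 went from 5.61 to 8.04 and UNG from 10.07 to 8.41 without overlap.

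**Figure D2:**
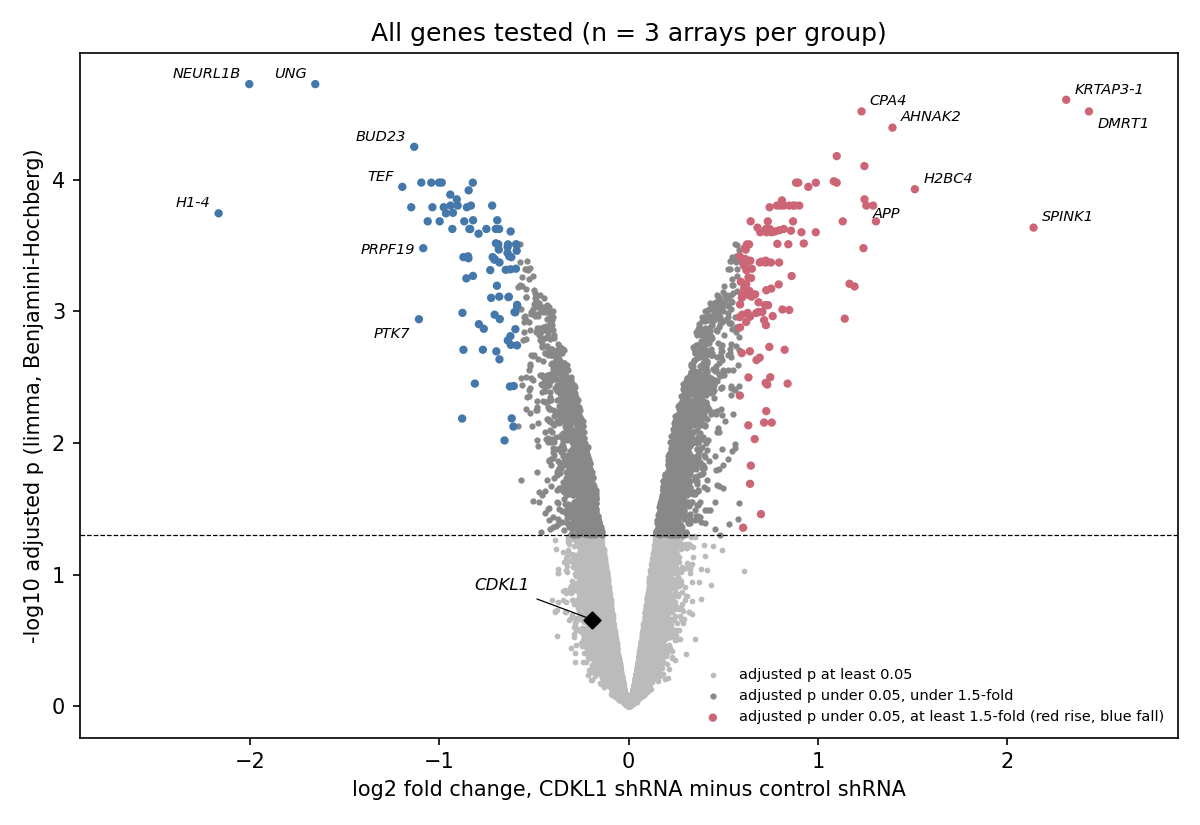
Log2 fold change of CDKL1 shRNA minus control shRNA (horizontal axis) against -log10 adjusted p from limma (vertical axis) for 18132 genes, with red and blue points for the 125 genes higher and 93 genes lower by at least 1.5-fold at an adjusted p under 0.05 (dashed line). CDKL1 (black diamond) lay at -0.19, above an adjusted p of 0.05.

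Of 30 gene lists fixed before the data were examined, 6 passed the threshold with camera at a preset correlation of 0.01, 3 shifted lower and 3 higher in CDKL1 shRNA arrays. With an estimated correlation 0 of these passed: adjusted p was 0.303 for cholesterol synthesis and 0.311 for each of the other 5 lists, and 4 lists had an unadjusted p under 0.05. All 6 passed with fry, which called 11 lists and tests whether genes of a list move one way without comparing them with other genes.

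The fixed lists of mitosis, DNA replication and cholesterol synthesis genes shifted lower at the preset correlation, though most of their members did not pass. In the G2/M and mitosis list 12 of 29 measured genes fell, 0 rose and 17 did not pass (camera adjusted p = 1.04e-05, and adjusted p = 0.311 with an estimated correlation), with a median log2 change of -0.17. Adjusted over the list alone, 17 fell. CENPF, a kinetochore protein gene, fell by 0.66 (SE 0.12). The mitotic kinase gene CDK1 fell by 0.25, its partner CCNB2 by 0.24 and the cytokinesis kinesin gene KIF20A by 0.26, each with an SE of 0.04 to 0.05. In the DNA replication and G1/S list 7 of 29 genes fell, 1 rose and 21 did not pass, with 4 falls after subtraction of each array's median (camera adjusted p = 0.0062, and adjusted p = 0.311 with an estimated correlation), with a median of -0.09. Adjusted over the list alone, 11 fell and 2 rose. Besides UNG, the thymidylate synthase gene TYMS fell by 0.30 (SE 0.04) and the clamp loader gene RFC4 by 0.28 (SE 0.05), whereas the phosphatase gene CDC25A rose by 0.30 (SE 0.06). In the cholesterol synthesis list 9 of 19 genes fell, 0 rose and 10 did not pass, also when adjusted over the list alone (camera adjusted p = 0.000358, and adjusted p = 0.303 with an estimated correlation), with a median of -0.14. HMGCS1, the synthase that makes HMG-CoA, fell by 1.04 (SE 0.06), the sterol-regulated INSIG1 by 0.57 (SE 0.05), and the sterol pathway enzyme genes NSDHL and MSMO1 each by 0.26 (SE 0.04). These shifts were measured on arrays whose ACTB 3' minus 5' difference was 0.198 higher in the CDKL1 shRNA group.

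Member counts of these 3 lists were lower in most fits with 1 array left out, which held fewer arrays. In these fits the list medians stayed at -0.186 to -0.137 for G2/M and mitosis and -0.117 to -0.0857 for DNA replication and G1/S. For cholesterol synthesis they stayed at -0.173 to -0.15. In the G2/M and mitosis list 7 genes fell without control replicate 2, 5 without control replicate 3, 7 without CDKL1 shRNA replicate 2 and 7 without CDKL1 shRNA replicate 3. In the DNA replication and G1/S list 4 fell without control replicate 1, 3 without control replicate 2, control replicate 3, CDKL1 shRNA replicate 1 or CDKL1 shRNA replicate 3. In the cholesterol synthesis list 5 fell without control replicate 3 and 4 without CDKL1 shRNA replicate 3. CDC25A lost its call without control replicate 3 (limma, adjusted p = 0.0532), CDKL1 shRNA replicate 2 (adjusted p = 0.0574) or CDKL1 shRNA replicate 3 (adjusted p = 0.0748). MSMO1 did not pass when its 4 probe sets were averaged (adjusted p = 0.0885). With the ACTB difference as a covariate the DNA replication and G1/S list did not pass (camera at the preset correlation, adjusted p = 0.185). The G2/M and mitosis list (adjusted p = 0.00257) and the cholesterol synthesis list (adjusted p = 0.00879) passed in this fit, which was not run with an estimated correlation.

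The fixed lists of NF-kappaB, autophagy and replication-dependent histone genes shifted higher at the preset correlation. In the NF-kappaB and inflammatory signalling list 7 of 21 genes rose and 0 fell, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0062, and adjusted p = 0.311 with an estimated correlation), with a median log2 change of 0.08. The 7 were the neutrophil-attracting chemokine genes CXCL3 (1.13, SE 0.07), CXCL8 (0.99, SE 0.05), CXCL2 (0.54, SE 0.05) and CXCL1 (0.44, SE 0.05), together with ICAM1 (0.48), TNFAIP3 (0.41) and CCL20 (0.37). CXCL1, CXCL2 and CXCL3 are close relatives and may share probe signal. In the same arrays 2 of 14 measured leukocyte marker genes rose, CD163 by 0.65 (SE 0.06), from a control level of 4.56 within the range of background controls, and CD68 by 0.39 (SE 0.08). In the autophagy and lysosome list 7 of 23 genes rose and 2 fell, and 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.311 with an estimated correlation), with a median of 0.13. With 1 array left out 5 to 7 of these genes rose and 2 fell. The unadjusted camera p with an estimated correlation was 0.045, and 0.172 after subtraction of each array's median. The autophagosome protein gene MAP1LC3B rose by 0.64 (SE 0.05), the autophagy receptor gene SQSTM1 by 0.57 (SE 0.04), the conjugation factor gene ATG12 by 0.50 (SE 0.05) and the lysosomal sialidase gene NEU1 by 0.43 (SE 0.04). The 2 that fell were the lysosomal channel gene MCOLN1 (-0.62) and GABARAPL1 (-0.41), a relative of MAP1LC3B. In the list of replication-dependent histones 7 of 12 genes rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0324, and adjusted p = 0.311 with an estimated correlation), with a median of 0.36. H2AC6 rose by 0.84 (SE 0.06), H3C4 by 0.72 (SE 0.07) and H2BC12 by 0.53 (SE 0.06), while the linker histone gene H1-2 fell by 0.73 (SE 0.07). With any 1 array left out, 7 of these histone genes rose and 1 fell. The list does not stand for all histone genes: over all 55 measured core histone cluster genes, grouped after the values were seen, 9 rose and 5 fell, with a median of -0.05, and 2 fell without control replicate 2 or any 1 of the CDKL1 shRNA replicates. Of 9 linker histone genes 0 rose and 3 fell. Without CDKL1 shRNA replicate 1 the histone list did not pass (adjusted p = 0.0898), and over genes brighter than the median gene neither the histone nor the autophagy list passed (adjusted p = 0.109 each). The ACTB difference of 0.198 between the groups holds for these lists too. With it as a covariate, camera at the preset correlation passed the NF-kappaB (adjusted p = 0.00185), autophagy (adjusted p = 0.00879) and histone (adjusted p = 0.00257) lists. The covariate was not combined with an estimated correlation, nor were these lists fitted with it without CDKL1 shRNA replicate 2.

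**Figure D3:**
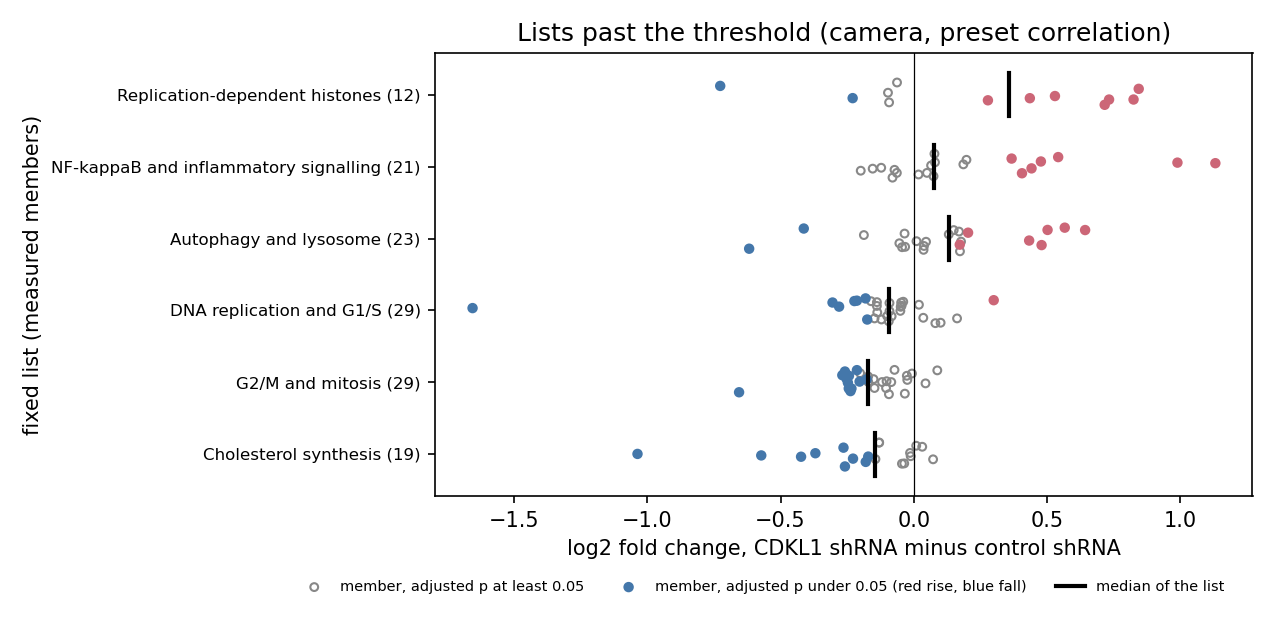
Log2 fold change of CDKL1 shRNA minus control shRNA (horizontal axis) for each measured member of the 6 lists past the threshold (vertical axis, with the number measured), filled where the member passed an adjusted p of 0.05 (red higher, blue lower); black lines are list medians. The medians ran from -0.17 for G2/M and mitosis to 0.36 for replication-dependent histones, and none of the 6 lists passed with an estimated correlation (adjusted p of 0.303 to 0.311).

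Genes of cell cycle arrest and cell death moved in both directions. In the list of cell cycle inhibitors and p53 targets 4 of 22 genes rose and 6 fell (5 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.614). The INK4 family inhibitor gene CDKN2B rose by 0.85 (SE 0.08), TP53I3 by 0.33 (SE 0.06) and the death receptor gene TNFRSF10B by 0.24 (SE 0.05), whereas the stress gene GADD45A fell by 0.59 (SE 0.06). In the apoptosis list 5 of 22 genes rose and 3 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.946). The pro-apoptotic BIK rose by 0.54 (SE 0.04), the cytochrome c gene CYCS by 0.24 (SE 0.04) and the caspase inhibitor gene XIAP by 0.24 (SE 0.05), while the caspase-8 regulator gene CFLAR fell by 0.25 (SE 0.05). Without CDKL1 shRNA replicate 3, TNFRSF10B (limma, adjusted p = 0.0527), CFLAR (adjusted p = 0.0538) and XIAP (adjusted p = 0.0685) did not pass, and XIAP was also lost without control replicate 2 (adjusted p = 0.0717), control replicate 3 (adjusted p = 0.0764) or CDKL1 shRNA replicate 1 (adjusted p = 0.0639). Averaging all probe sets of a gene also ended the calls of TNFRSF10B (adjusted p = 0.155) and CFLAR (adjusted p = 0.0639). In the DNA damage repair list 2 of 19 genes rose and 4 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.614, but fry adjusted p = 0.0225), with rises of XRCC2 (0.79, SE 0.05) and PALB2 (0.27, SE 0.04) and falls of RAD54L (-0.33, SE 0.04) and FANCI (-0.30, SE 0.05).

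Neither the epithelial nor the colonocyte list passed with camera. In the epithelial junction and keratin list 5 of 22 genes rose and 1 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.614, but fry adjusted p = 0.0262). The tight junction genes CLDN1 (0.99, SE 0.07), OCLN (0.41, SE 0.05) and CLDN3 (0.33, SE 0.05) rose, as did the keratin gene KRT20 (0.52, SE 0.05), which also stands in the colonocyte list. Of 24 colonocyte differentiation genes 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.946): KRT20 and the trefoil factor gene TFF3 (0.43, SE 0.07) were higher, the microvillus protein gene VIL1 (-0.57, SE 0.12) and the carbonic anhydrase gene CA2 (-0.21, SE 0.05) lower. VIL1 lost its call without control replicate 1 (limma, adjusted p = 0.0639) or control replicate 3 (adjusted p = 0.0601). CA2 lost it without any 1 of the arrays apart from CDKL1 shRNA replicate 2, with adjusted p of 0.0651 to 0.12. Of 22 Wnt/beta-catenin targets 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.614). MYC rose by 0.24 (SE 0.04), the stem cell receptor gene LGR5 fell by 0.36 (SE 0.06) and TNFRSF19 by 0.49 (SE 0.05), and RNF43 had a log2 change of -0.16 that did not pass (adjusted p = 0.0627) but passed after a further quantile normalisation (adjusted p = 0.0339). Of 23 mesenchymal and invasion genes 0 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.76). Those were PLAU and TGFBI, at -0.34 each, named after their values were seen.

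Signalling and ciliary lists did not pass as groups. Of 23 genes of MAPK pathway output 3 rose and 6 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.972). JUN rose by 0.87 (SE 0.05), whereas the immediate-early genes IER3 (-0.64, SE 0.04) and EGR1 (-0.41, SE 0.05) and the ERK phosphatase gene DUSP6 (-0.43, SE 0.05) fell. Of 27 genes of the type I interferon response 6 rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.614), with rises of ISG15 (0.62, SE 0.05), ISG20 (0.62, SE 0.05) and IRF7 (0.35, SE 0.04) and a fall of HERC5 (-0.32, SE 0.04). Of 29 cilium and intraflagellar transport genes 2 rose and 4 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.946). IFT20 rose by 0.54 (SE 0.05) and IFT27 by 0.28 (SE 0.05), whereas WDR35 fell by 0.34 (SE 0.07) and IFT22 by 0.22 (SE 0.05). WDR35 was not called without control replicate 2 (limma, adjusted p = 0.0677), control replicate 3 (adjusted p = 0.0578) or CDKL1 shRNA replicate 3 (adjusted p = 0.0673), nor IFT22 without CDKL1 shRNA replicate 3 (adjusted p = 0.069). In the Hedgehog list 0 of 14 genes rose and 1 fell (camera adjusted p = 0.614), namely the receptor gene PTCH1 at -0.23, named after its value was seen.

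Stress and metabolic genes also moved in both directions. In the unfolded protein response list 5 of 23 genes rose and 4 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.697). HERPUD1, of the degradation machinery of the endoplasmic reticulum, rose by 0.75 (SE 0.05) and the co-chaperone gene DNAJB9 by 0.36 (SE 0.05), whereas PDIA3 (-0.42, SE 0.06) and SDF2L1 (-0.41, SE 0.05) fell. Of 24 genes of the ATF4 and amino acid response 4 rose and 4 fell (5 and 5 adjusted over the list alone, camera adjusted p = 0.946). The mTORC1 inhibitor gene DDIT4 fell by 0.99 (SE 0.05), TRIB3 by 0.70 (SE 0.05) and the serine synthesis gene PHGDH by 0.28 (SE 0.04), and ATF3 rose by 0.42 (SE 0.05) in its brightest probe set but did not pass when its 7 probe sets were averaged (limma, adjusted p = 0.1). Of 23 glycolysis and hypoxia genes 6 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.614). ADM (0.33, SE 0.04) and the collagen prolyl hydroxylase gene P4HA1 (0.38, SE 0.06) rose, and EGLN3 fell by 0.34 (SE 0.05), which did not pass with its probe sets averaged (adjusted p = 0.113). PFKFB3 had 0.31 (SE 0.04) in its brightest probe set but negative changes in its other 3, and with their mean the change was -0.02 (adjusted p = 0.778). In the oxidative stress (NRF2) list 7 of 20 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.101, but fry adjusted p = 0.0262). AKR1C3 rose by 0.73 (SE 0.11), the glutathione synthesis gene GCLM by 0.31 (SE 0.04), SRXN1 by 0.29 (SE 0.04) and the ferritin light chain gene FTL by 0.21 (SE 0.04), and with the mean of all probe sets the list passed (adjusted p = 0.0154).

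Of 24 ribosome biogenesis and MYC target genes 4 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.101): PES1 (0.37, SE 0.05), RRP12 (0.30, SE 0.05), POLR1B (0.25, SE 0.06) and GAR1 (0.24, SE 0.04). POLR1B lost its call without any 1 of the arrays apart from CDKL1 shRNA replicate 2, with limma adjusted p of 0.0583 to 0.114. Of 17 heat shock genes 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.652). These were the co-chaperone genes DNAJB4 (0.75, SE 0.07), CHORDC1 (0.26, SE 0.06) and DNAJA1 (0.21, SE 0.04), and HSPE1 had -0.15 (adjusted p = 0.102, and 0.0465 after a further quantile normalisation). CHORDC1 was not called without any 1 of the arrays apart from control replicate 2, with adjusted p of 0.0585 to 0.106, and DNAJA1 was not called without CDKL1 shRNA replicate 3 (adjusted p = 0.0612). Of 23 oxidative phosphorylation genes 0 rose and 2 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.191, but fry adjusted p = 0.0225). Those were NDUFB5 (-0.18) and UQCRC1 (-0.17), named after their values were seen. Of 14 genes of the RNA interference machinery limma called 0, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.972).

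Markers of other cell types were low in number among the called genes. Besides CD163 and CD68 among 14 leukocyte markers (camera adjusted p = 0.614, but fry adjusted p = 0.00668, 1 of the 11 lists that fry called), limma called POSTN (0.23, SE 0.06) among 14 fibroblast markers (camera adjusted p = 0.946) and ENO2 (0.28, SE 0.08) among 13 kidney-line and neural markers (camera adjusted p = 0.614), and these 4 genes were named after their values were seen. Both group means of POSTN, 4.35 and 4.57, lay within the range of background controls, so its call does not show expression. Adjusted over the list alone, both leukocyte markers remained called, and 0 of the fibroblast and 0 of the neural markers were. ENO2 also stands in the glycolysis list. Of 12 endothelial markers limma called 0, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.972). In 6 lists the median, the mean and the direction of the test differed in sign, namely the epithelial, colonocyte, MAPK, ATF4, heat shock and RNA interference lists, and 0 of these had passed.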

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

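The tests of the CDKL1 probe set, of a 3' shift and of chromosomes were chosen only after the results were seen, whereas the splits of the arrays were planned.

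Probe sets outside the gene tests also carried signal, by a limma fit over 49293 probe sets. Of the 1832 probe sets with several gene symbols, 20 were higher by at least 1.5-fold in CDKL1 shRNA arrays and 4 lower, and the largest rise was that of 11742315_s_at, by 1.95 on the log2 scale (SE 0.196, adjusted p = 0.00149). Of the 2473 probe sets with no gene in the annotation table, 10 were higher by at least 1.5-fold and 8 lower, and the largest rise was that of 11730477_at, by 0.984 (SE 0.0773, adjusted p = 0.000575).

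The CDKL1 probe set was not lower past the threshold in arrays labelled CDKL1 shRNA, with a log2 change of -0.19 and a 95% interval from -0.41 to 0.03. Its mean of 4.271 lay within the range of 2.97 to 4.92 of background control probe sets with 10 to 16 G or C bases, so it may read mostly background. The base composition of its probes is not known here, and background reached 10.7 at 25 G or C bases, so background cannot be told apart from a true but low CDKL1 signal. Of the 1017 genes within 0.25 of its mean, limma called 19 lower and 7 higher, so calls at this level were few. Incomplete loss of the transcript stays open as the biological explanation and was not tested.

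The large number of called genes was set against chance, a 3' shift of the RNA and copy number. With 10 splits of the arrays no share under 0.05 can be reached: the real split was the 1 split that reached 3040 genes, 218 genes at 1.5-fold and 6 lists, and the highest of the other splits gave 0, 0 and 3 (limma, with 340 to 775 genes at an unadjusted p under 0.05, against 5407). With the ACTB difference as covariate, the 93 genes that fell at least 1.5-fold had a median ratio of covariate to plain log2 change of 1.03. With the covariate change fitted without CDKL1 shRNA replicate 2, and the plain change still from all 6 arrays, this ratio was 1.14. For the 125 that rose it was 0.99 with all arrays but 0.822 without that replicate, with a lower quartile of 0.496. The ACTB difference was 1.73 in that replicate, 1.52 and 1.55 in the other CDKL1 shRNA arrays and 1.39 to 1.41 in control arrays. The covariate thus rested largely on 1 array and otherwise followed the groups, so the 3' shift stays open for rises and falls. For the G2/M and mitosis list the group coefficient with the covariate was -0.177 (95% interval -0.295 to -0.0583) against -0.159 without it. Without CDKL1 shRNA replicate 2 it was -0.241 (-0.834 to 0.352). The estimate did not shrink, but the interval without that replicate was too wide to tell a 3' shift and an effect of the shRNA apart. Medians of 23 chromosomes lay between -0.03 and 0.0102, which argues against a gained or lost whole chromosome, and effects of CDKL1 loss, of other targets of the shRNA or of the cell population stay open as untested.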

How the results depend on the processing

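The direction of the CDKL1 change and of both RNA quality differences held under the alternatives run for them. The split of called genes into higher and lower turned under a further quantile normalisation (1542 higher, 1689 lower) and under the ACTB covariate. The split of genes changed at least 1.5-fold turned under the ACTB covariate (87 higher, 89 lower). The cause of shifts in counts was not tested unless stated. The 3040 called genes became 1633 to 2399 with 1 array left out, 1289 at an adjusted p of 0.01, a stricter threshold by construction, and 219 with the ACTB covariate (109 higher, 110 lower), chosen after seeing the data, where genes that rose and fell at least 1.5-fold had median ratios of covariate to plain change of 0.99 and 1.03 and the median SE of the rises went from 0.0586 to 0.106. Replicate numbers did not pair the samples, since deviations of same-numbered arrays correlated at -0.029, -0.121 and 0.070, and with the replicate block the count was 1803, 1024 higher and 779 lower, with 1760 genes shared, while 6 lists passed as without it. Other settings gave 2337 to 4201 genes. The 218 genes at 1.5-fold became 207 to 229 with 1 array left out and 176 with the ACTB covariate. They became 134 with the mean of probe sets (81 higher, 53 lower). With every probe set they became 372 (230 higher, 142 lower), where any of several probe sets can bring a call. The 6 lists became 5 to 6 with 1 array left out, 0 with an estimated correlation and 11 with fry. CDKL1 ranged from -0.293 (adjusted p = 0.0489, without control replicate 3) to -0.121, the ACTB difference from 0.132 to 0.239 and the GAPDH difference from 0.0611 to 0.0866. PFKFB3 reversed to -0.0194 with the mean of its probe sets. Values of other named genes and lists kept their direction and side of the threshold in 1589 and 375 fits, lost a call in 113 and 10, gained one in 9 and 6 and changed sign without a call in 3 and 24. Of 103 called named genes, 11 lost the call without at least 1 array and 62 with the ACTB covariate, where the median ratio of covariate to plain change of these 62 was 0.96. Signal over background limits dim genes such as CDKL1.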

Other observations

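All genes and tests in this part were chosen after the values were seen.

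Genes of transport between the endoplasmic reticulum and the Golgi, and of Golgi structure, stood out among the rises. A list of 140 such genes was written after 21 of them had been noticed, and of 135 measured, 71 rose and 10 fell by limma, with a median log2 change of 0.21. With 1 array left out 56 to 66 rose, and the number that fell was 5 without control replicate 2, control replicate 3 or CDKL1 shRNA replicate 1 and 3 without CDKL1 shRNA replicate 3. The cargo receptor gene LMAN1 rose by 1.19 (SE 0.10), the golgin-45 gene BLZF1 by 1.10 (SE 0.04), the small GTPase gene ARF4 by 0.88 (SE 0.05), the KDEL receptor gene KDELR3 by 0.86 (SE 0.06), and YIF1A and the SNARE gene GOSR2 each by 0.82 (SE 0.05). Of 18 coat subunit genes in this list 11 rose, 2 fell and 5 did not pass, and 1 fell without control replicate 3, CDKL1 shRNA replicate 1 or CDKL1 shRNA replicate 3. The largest rises were those of SEC31A (0.64), COPA (0.63) and SEC24A (0.62), and the falls were those of SEC23A (-0.65, SE 0.05) and SEC31B (-0.32). ARF5 fell by 0.57 (SE 0.05). CREB3, a Golgi-processed transcription factor gene, rose by 0.73 (SE 0.06), and its relative CREB3L2 fell by 0.62 (SE 0.05).

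Counts within 7 gene families gave no family past an adjusted p of 0.05 (camera in limma with an estimated correlation, adjusted over the 7 families). The integrin family held 26 genes picked by symbol, among them the integrin-like gene ITGBL1 (-0.028). Of these, 0 rose and 5 fell with all arrays (ITGA3, ITGA7, ITGA9, ITGB5 and ITGB8, camera adjusted p = 0.0707). There were 3 falls without control replicate 1, control replicate 2 or CDKL1 shRNA replicate 3. Without CDKL1 shRNA replicate 1, 3 fell and 1 rose. Of the 4 inhibitor of DNA binding genes ID1, ID2 and ID3 fell, with a median of -0.38 (adjusted p = 0.0707). Of 18 ATG autophagy genes 5 rose and 0 fell (adjusted p = 0.0707). Of 9 linker histone genes 0 rose and 3 fell (adjusted p = 0.148), whereas of 55 core histone genes 9 rose and 5 fell (adjusted p = 0.98), with 2 falls without control replicate 2 or any 1 of the CDKL1 shRNA replicates. Of 82 keratin-associated protein genes 4 rose and 0 fell (adjusted p = 0.98). Among 451 zinc finger genes 57 rose and 13 fell with all arrays (adjusted p = 0.148), against 24 and 8 without CDKL1 shRNA replicate 3, 27 and 11 without control replicate 3, 34 and 6 without control replicate 2, and 40 and 8 without CDKL1 shRNA replicate 1. Outside these families, the fatty acid desaturase gene SCD fell by 0.79 (SE 0.05), as did the single genes CORO1A (-0.68), TAGLN2 (-0.64) and TLN1 (-0.62). The phosphatase gene DUSP1 rose by 1.08 (SE 0.05), the transporter gene ABCG2 by 0.93 (SE 0.06) and the surface marker gene PROM1 by 0.91 (SE 0.06).

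A hypothesis is that the rise of ER-to-Golgi and Golgi genes is a coordinated response of the CDKL1 shRNA cells. The 114 measured members not noticed beforehand also shifted upwards, so the shift was not confined to the noticed genes. Of these 114, 51 rose and 9 fell, with a median of 0.155 and a camera p of 0.0194 with an estimated correlation. They were read on the same arrays from which the theme was chosen, and this p is not adjusted for that choice. Selection of the theme by its values therefore stays open. For these 114 members the camera p with an estimated correlation was 0.133 after subtraction of each array's median (0.0845 for all members), 0.0555 without control replicate 1 and 0.0514 without control replicate 2. Their median log2 change in these fits was 0.168, 0.165 and 0.162, so the shift itself was not smaller. In the remaining fits this camera p was lower than 0.05. It was 0.00874 after a further quantile normalisation, 0.00267 without CDKL1 shRNA replicate 1, and 0.0308 to 0.0462 without any 1 of the other arrays. A 3' shift of the RNA was tested with the ACTB difference as a covariate over all 135 measured members, including the 21 noticed beforehand. It was not tested for the 114 alone. Over the 135 members the group coefficient was 0.219 (95% interval 0.158 to 0.28) with all arrays, against 0.228 without the covariate. Without CDKL1 shRNA replicate 2 it was 0.159 (-0.0994 to 0.417). In the arrays then left, the ACTB difference followed the groups, at 1.39 to 1.41 in controls against 1.52 and 1.55, so little spread within groups remained. A 3' shift may therefore still contribute and cannot be told apart from an effect of the shRNA. Whether any such response comes from loss of CDKL1 or from other targets of the shRNA was not tested.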
